A study of Mus musculus with 24 samples.

How the data were processed

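Messenger RNA from the cortex of mice aged 7.5 months was sequenced in 24 libraries. The 3 genotypes, with 8 libraries each, were 5xFAD, 5xFADM28L and 5xFADP522R. Mice of the 5xFAD line carry human transgenes with familial Alzheimer's disease mutations, APP among them, expressed under the Thy1 promoter, and form amyloid plaques. The other genotypes carried in addition a variant of Plcg2, the gene of phospholipase C-gamma-2, a signalling enzyme downstream of microglial and B cell receptors. Per the labels, both variants were homozygous. Each title held the letter F or M, with 4 libraries of each letter per genotype, and an animal number that is used here as the replicate name. Some animals of different genotypes share a letter-and-number prefix in their titles, but the labels do not say what it marks, and it was not taken to pair them. The animal numbers differ from library to library, so each library was taken as 1 mouse.

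Per the labels' protocols, RNA was isolated by chloroform extraction with a column kit and libraries were made with the KAPA mRNA HyperPrep kit. Per the submitters' processing notes, the tools were STAR 2.7.2b and featureCounts, whose version is not given in the sources used here. The genome build, the annotation and the strand setting of the counting are likewise not given in the sources used here. The deposited table held whole-number read counts per gene for every library, not normalized, with gene coordinates and exon lengths. Of its 53647 gene identifiers, 52093 (97.1%) matched GENCODE M21, which supplied symbols, gene types and transcript GC content. Only 2.8% of the genes had the same start and end in M21 on GRCm38. Coordinates are therefore printed as the deposited table gives them, in a build it does not name. Because the strand setting was unknown, reads of overlapping and antisense genes could not be told apart. Reads of near-identical copies, such as the H2 genes or Rpl41 and its pseudogenes, may have been split or lost in the authors' counting.

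Total counts ran from 79230161 to 115154197 per library. Among 276 pairs of libraries none had identical counts, and the smallest chi-square per degree of freedom was 7.15, so no library was counted as a copy of another. Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, filterByExpr on genotype) in R 4.3.3, which left 21280 genes. All 24 libraries entered one fit with genotype and title letter as terms. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold. Fold changes are log2 values with standard errors (SE). Levels are given in CPM, counts scaled to TMM-adjusted library size, as mean ± SD. A further fit held the interaction of genotype and letter. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with adjustment over 32 lists, and again with the correlation estimated per list. Each list also had a score per mouse, the mean of the z-scored log2 CPM of its genes (prior count 2), compared between genotypes by exact two-sided permutation. With 8 against 8 libraries the smallest p such a test can give is 0.00016.

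The lists, the tests, the covariates and the rule for genes to name were set before the data were examined. The 32 lists covered microglial states and functions, lipid and cholesterol genes, orthologs of Alzheimer's risk genes, markers of the other brain cell types and of blood, border tissue and brain regions near the cortex, immediate early genes, the cell cycle and mitochondrially encoded genes. The text could name Plcg2, App and Thy1, then up to 10 genes with the largest rise and 10 with the largest fall at a mean of at least 1 CPM. It could also name up to 4 members of each list by smallest p, and Xist and Y-linked genes for the letters. Predicted gene models were left out of the ranking, and not all genes that the rule allowed are named. Some of them are not reported here. Genes outside the rule are marked as chosen after their values were seen or as taken by position.

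The pipeline was tested on counts simulated from the real means and library sizes with 100 genes changed by each of 2 sizes. For M28L against 5xFAD it recovered 74% of genes changed by 0.5 on the log2 scale and 99% of those changed by 1, over 20996 genes tested. The shares were 64% and 99% for P522R against 5xFAD, and 76% and 99% for P522R against M28L. False calls made up 2.81%, 5.23% and 5.41% of all calls. The simulated genes varied independently of each other, so these shares do not cover variation that many genes of a library have in common. The same GC trend was then added to every simulated P522R library. There 2464 false calls made up 93.2% of the calls of P522R against 5xFAD over 20929 genes. With offsets for GC content and gene length 7 made up 3.95% over 20856 genes.

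The alternatives tried were DESeq2 1.42.0, limma-voom with sample weights, RLE and upper-quartile factors, no filter on low counts, a filter at a mean of 1 CPM, a fit without the letter, fits of 2 genotypes or of 1 letter, 1 and 2 surrogate variables (sva 3.50.0), the title prefix as a block, and each library left out in turn. After the data had been seen, 5 alternatives were added: offsets for GC content and gene length, leaving out M28L replicate 28 and P522R replicate 31, leaving out 5 libraries with over 10% of reads on Bc1, levels for reads on Y-linked genes in F libraries, and the log2 Bc1 share as a covariate. The set of 5 libraries was first drawn up from P522R alone and was widened, before it was run, to include the 5xFAD library past the same limit.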

Results

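Read counts were measured in the cortex of 7.5-month-old 5xFAD mice and of 5xFAD mice homozygous for the M28L or the P522R variant of Plcg2. Each genotype had 8 libraries, 4 with the title letter F and 4 with M. Total counts ran from 79230161 to 115154197 per library in 5xFAD, from 92358031 to 111292787 in M28L and from 94698916 to 106089349 in P522R. Xist, the RNA that silences an X chromosome, lay between 170 and 420 CPM in the F libraries and at most at 1.86 CPM in the M libraries. The Y-linked gene Ddx3y lay between 32.7 and 52.3 CPM in the M libraries and at most at 0.328 CPM in the F libraries, so all letters matched these genes. Fewer genes were detected in P522R, 25118 ± 1200, and in M28L, 27221 ± 1047, than in 5xFAD, 28368 ± 366. Both differences passed an exact permutation test adjusted over 24 tests of library measures (adjusted p = 0.0037 and 0.020). Bc1, a short neuronal RNA, took 10.2 ± 4.55% of the counts in P522R, 5.81 ± 2.14% in 5xFAD and 4.0 ± 0.922% in M28L. The Bc1 share differed between P522R and M28L (exact permutation, adjusted p = 0.0037), and not past the threshold between P522R and 5xFAD (adjusted p = 0.054).

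Plcg2 itself (ENSMUSG00000034330.11, chromosome 8, 118225030 to 118361881 in the coordinates of the deposited table) was higher in P522R. It was counted at 9.38 ± 2.61 CPM in 5xFAD, 8.69 ± 1.96 CPM in M28L and 19.5 ± 6.50 CPM in P522R (SD, n = 8 each). The difference was 1.04 on the log2 scale (SE 0.14) between P522R and 5xFAD, with edgeR's adjusted p = 5.6e-06, and all 8 P522R libraries exceeded the 5xFAD mean. Between P522R and M28L it was 1.15 (SE 0.14, adjusted p = 1.4e-06). M28L did not differ detectably from 5xFAD, at -0.11 (SE 0.14, adjusted p = 0.86). An exact permutation test of log2 CPM gave p = 0.00078, 0.00047 and 0.62 for these comparisons. With the log2 Bc1 share as a covariate, an alternative chosen after the data were seen, the difference between P522R and M28L was 0.89 (SE 0.27) and did not pass (adjusted p = 0.26). These counts say nothing about the coding change itself. App, whose human transgene can add reads to the mouse gene, lay at 1855 ± 274 CPM in 5xFAD. It differed from 5xFAD by 0.10 in M28L (adjusted p = 0.68) and by 0.00 in P522R (adjusted p = 0.97). Thy1, whose promoter drives the transgene, differed from 5xFAD by -0.21 in M28L (adjusted p = 0.38) and by 0.06 in P522R (adjusted p = 0.70). Thy1 was 0.26 higher in P522R than in M28L (SE 0.09, adjusted p = 0.029), a call lost under 15 other settings, among them leaving out M28L replicate 28 or P522R replicate 31 or 106 (adjusted p = 0.056 to 0.081). App differed by -0.10 there (adjusted p = 0.28).

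**Figure D1:**
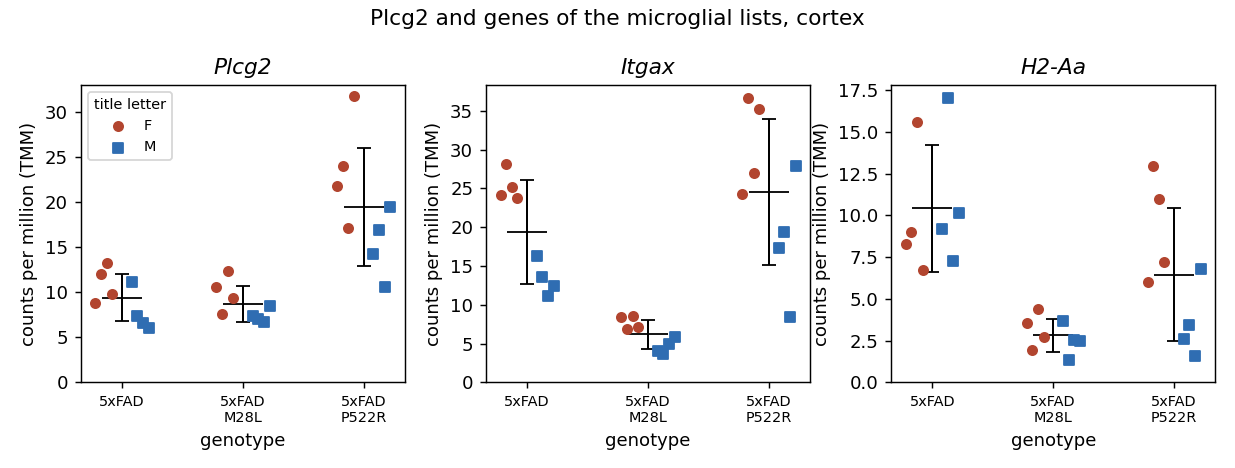
CPM (TMM-scaled) of Plcg2, Itgax and H2-Aa in each library, by genotype; circles are F and squares M libraries, and the black bars give the mean and SD of 8 libraries. Plcg2 averaged 19.5 CPM in P522R and 9.38 CPM in 5xFAD, and Itgax averaged 6.18 CPM in M28L and 19.3 CPM in 5xFAD.

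The comparison of M28L with 5xFAD asks what this variant changes in a brain with amyloid plaques. Genes of disease-associated microglia, the state that microglia take up around plaques, were lower in M28L. Itgax, an integrin of that state, fell by 1.62 (SE 0.16, adjusted p = 4.8e-07), from 19.3 ± 6.70 to 6.18 ± 1.86 CPM. Gpnmb, a lysosome-associated glycoprotein, fell by 1.61 (SE 0.23), and Lilrb4a, an inhibitory receptor, by 1.91 (SE 0.20). Of the 34 tested genes of this list 16 fell and 0 rose, against 25 that fell when adjusted over the list alone. The list fell as a set (adjusted p = 3.2e-42, and adjusted p = 0.0034 with an estimated correlation), and its median log2 difference was -0.56. Antigen presentation genes were lower too. H2-Aa fell by 1.92 (SE 0.30), H2-Ab1 by 1.63 (SE 0.27) and Cd74, the chaperone of class II molecules, by 1.76 (SE 0.28). Of 22 genes in that list 11 fell, or 19 adjusted over the list alone, with a median of -0.62 (adjusted p = 0.0042 with an estimated correlation). H2 genes share sequence with their paralogs, so single H2 values are uncertain.

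Other myeloid lists were lower in M28L as well. Of 22 pan-myeloid genes 3 fell (Csf3r, Ptprc and Spi1), or 20 adjusted over the list alone, with a median of -0.42 (adjusted p = 0.018 with an estimated correlation). The Spi1 call, at -0.54, was lost without any 1 of 6 libraries, 5xFAD replicates 1177, 1181, 1190 and 1248 and M28L replicates 9 and 14 (adjusted p = 0.052 to 0.068), and under 6 other settings. Of 32 genes around Plcg2 signalling 4 fell, or 14 adjusted over the list alone (adjusted p = 0.018 with an estimated correlation). They were Tlr2 at -0.74, Fcgr2b at -0.63, and the receptor Trem2 and its adaptor Tyrobp at -0.74 and -0.67. Complement genes fell as a list (adjusted p = 0.016 with an estimated correlation) through Itgax and C3ar1, with 2 of 18 called and 9 adjusted over the list alone. In the list of inflammatory cytokines and their receptors 5 of 28 genes fell, among them Ccl3 by 1.36 and Cd14 by 0.87. Adjusted over the list alone 6 fell and 1 rose (adjusted p = 0.016 with an estimated correlation). The T cell list fell as a set with 0 of 14 genes called, also 0 adjusted over the list alone (adjusted p = 0.023 with an estimated correlation). Csf3r, Ptprc, Spi1, Tlr2, Fcgr2b, Trem2, Tyrobp, C3ar1, Ccl3 and Cd14 were not called in a fit without the letter or in M libraries alone. In F libraries alone Csf3r, Ptprc, Spi1, Tlr2, Fcgr2b and C3ar1 were not called. With the Bc1 share as a covariate Csf3r, Spi1, Fcgr2b, Trem2 and Tyrobp were not called, and with levels for Y-linked reads Csf3r, Ptprc, Spi1, Fcgr2b and Trem2 were not. With the title prefix as a block Ptprc and Spi1 were not called.

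Calls of several other lists rested on the preset correlation. Homeostatic microglia genes had a median of -0.14, with Cx3cr1 called at -0.52, 1 of 25, and 4 adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). Lysosome genes had 7 of 34 lower, 14 adjusted over the list alone (adjusted p = 0.084 with an estimated correlation). Atp6v0d2, a subunit of the vacuolar proton pump, fell by 3.94 (SE 0.40), from 0.811 ± 0.565 to 0.0481 ± 0.0462 CPM. Interferon response genes had 2 of 34 lower, 9 adjusted over the list alone (adjusted p = 0.084 with an estimated correlation). Reactive astrocyte genes had 4 of 27 lower, with 7 lower and 3 higher adjusted over the list alone (adjusted p = 0.35 with an estimated correlation), and the list was called under 11 of 18 other settings. Among them Gfap, the astrocyte filament protein, lay at -0.60 (SE 0.15, adjusted p = 0.036). That call was lost under 15 other settings, 10 of them with 1 library left out, 5xFAD replicates 1177, 1180, 1181, 1190 and 1248 and M28L replicates 9, 11, 12, 14 and 15 (adjusted p = 0.060 to 0.10). Endothelial genes had 1 of 19 lower, Cldn5, also 1 adjusted over the list alone (adjusted p = 0.36 with an estimated correlation). Orthologs of Alzheimer's risk genes had 2 of 29 lower, Trem2 and Spi1, also 2 adjusted over the list alone (adjusted p = 0.20 with an estimated correlation), and were called under 12 of 18 other settings. Myelin genes were lower as a list with 0 of 23 called, also 0 adjusted over the list alone (adjusted p = 0.30 with an estimated correlation). The myelin list was called under 11 of 18 other settings.

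Meninges and fibroblast genes and immediate early genes were higher in M28L than in 5xFAD. With the preset correlation both lists were also called higher in P522R against the same 5xFAD libraries, so these list rises were not particular to M28L. The largest rises included Thbs1, a matrix glycoprotein outside the lists (ENSMUSG00000040152.9, chromosome 2, 117942357 to 117957614), which rose by 2.89 (SE 0.35, adjusted p = 1.4e-05), from 1.37 ± 0.211 to 11.5 ± 8.34 CPM. Tnc, also outside the lists, rose by 1.27 (SE 0.24), a call lost in M libraries alone, with the title prefix as a block, with levels for Y-linked reads and with the Bc1 share as a covariate. Col1a1, of the meninges and fibroblast list, rose by 1.48 (SE 0.18). Of 17 meninges and fibroblast genes 5 rose, or 11 adjusted over the list alone (adjusted p = 0.016 with an estimated correlation). Of 30 immediate early genes, which neurons induce on activity, 6 rose, or 17 adjusted over the list alone (adjusted p = 0.023 with an estimated correlation). Among these Nr4a3 rose by 0.88 and Egr1 by 0.62. The thalamus list rose with 2 of 15 genes, Rgs16 and Calb2, or 4 adjusted over the list alone (adjusted p = 0.031 with an estimated correlation). Both calls were lost without 5xFAD replicate 1180 or M28L replicate 12, that of Calb2 also without 5xFAD replicate 1190 and that of Rgs16 without M28L replicate 9 (adjusted p = 0.055 to 0.062). Neither was called without the letter, in M libraries alone, with the prefix as a block or with the Bc1 share, nor Rgs16 in F libraries alone, nor Calb2 with levels for Y-linked reads or without 5 libraries high in Bc1. Choroid plexus genes were higher through 1 of 15, Otx2 at 2.02 (adjusted p = 0.035), or 12 adjusted over the list alone. The Otx2 call was lost under 17 other settings, 9 of them with 1 library left out, M28L replicates 17 and 28 and 5xFAD replicates 1177, 1180, 1189, 1190, 1248, 1269 and 1270 (adjusted p = 0.053 to 0.16, with 1.39 without replicate 17). In the score of this list M28L replicate 17 scored 2.78 against at most 0.276 in the other M28L libraries (adjusted p = 0.12 with an estimated correlation). Cell cycle genes had 1 of 20 higher, Mki67, or 2 adjusted over the list alone (adjusted p = 0.12 with an estimated correlation).

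In all 258 of 21280 genes differed between M28L and 5xFAD, 107 higher and 151 lower. Of the 32 lists 19 were called, and 10 of them also with an estimated correlation. By score per mouse, with exact permutation adjusted over the lists, antigen presentation was lower, by -1.17 (adjusted p = 0.012). Immediate early, choroid plexus, meninges and thalamus scores were higher, and disease-associated microglia missed the threshold at -0.83 (adjusted p = 0.085), in a test without the letter. Of the calls 41.5% were higher with TMM, 30.1% with upper-quartile factors, 57.0% with limma-voom, 58.1% with 2 surrogate variables and 9.9% with the title prefix as a block. The gene count was 157, 158, 160 and 163 without 5xFAD replicate 1190, 1180, 1248 or 1181. It was 49 without the letter, 72 with the Bc1 share as a covariate, 98 with levels for Y-linked reads, 101 with the prefix as a block, 102 in F libraries alone and 5 in M libraries alone. It was 406 and 1347 with 1 and 2 surrogate variables, 543 with DESeq2, 628 with GC and length offsets, 707 with only these genotypes and 1937 with limma-voom. Itgax, Gpnmb, H2-Aa, H2-Ab1, Cd74, Cx3cr1, Cldn5, Thbs1, Col1a1, Nr4a3, Egr1 and Mki67 were not called in M libraries alone. H2-Ab1, Cx3cr1 and Cldn5 were not called in F libraries alone either, Cx3cr1 and Nr4a3 not without the letter, and Col1a1, Mki67 and Cldn5 not with the block. Mki67 was not called with levels for Y-linked reads, nor Cldn5 with the Bc1 share.

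**Figure D2:**
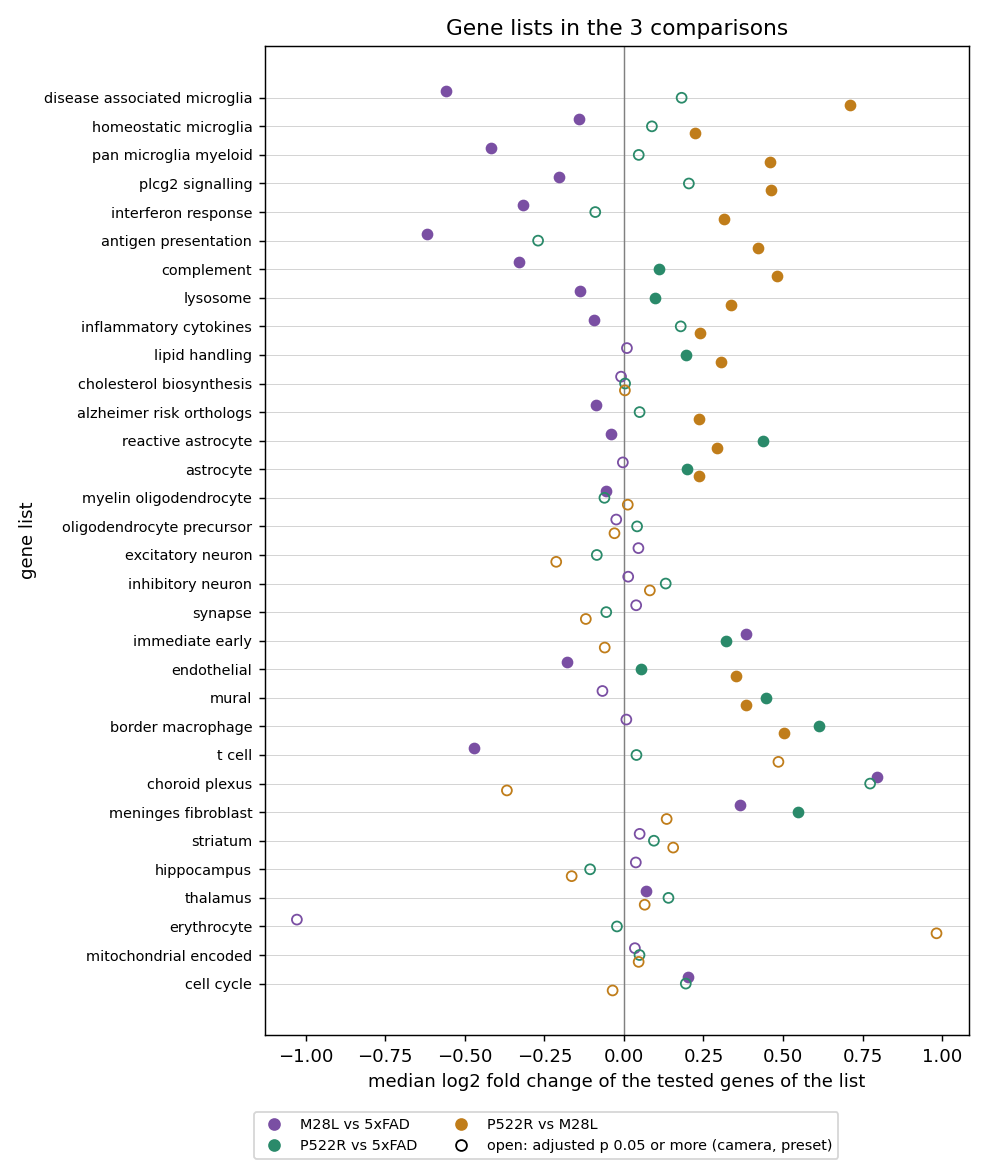
Median log2 fold change of the tested genes of each of 32 lists (horizontal axis) in the 3 comparisons; filled points passed camera with the preset correlation at an adjusted p below 0.05. The disease-associated microglia list had a median of -0.56 in M28L against 5xFAD and 0.71 in P522R against M28L.

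In the comparison of P522R with 5xFAD, which asks the same of the other variant, many genes differed by small amounts. Plin4, a lipid droplet coat protein, rose by 2.27 (SE 0.30, adjusted p = 5.4e-06), from 2.51 ± 1.17 to 12.1 ± 4.50 CPM. Foxc2 rose by 1.63 (SE 0.16), the small heat shock protein Hspb1 by 1.48 (SE 0.19) and Hif3a by 1.33 (SE 0.19). Among the largest falls was Tgfbr3l at -1.20 (SE 0.19). Rpl41 was 1.34 higher (SE 0.18), an uncertain value because pseudogene copies share its reads. Sftpc was 1.82 higher (SE 0.50) with only 4 of 8 libraries above the 5xFAD mean, and lay at -0.13 without 5 libraries in which Bc1 took over 10% of reads. H2-Aa lay at -0.82 (SE 0.29, adjusted p = 0.035), with 6 of 8 libraries below the 5xFAD mean, at -0.02 in F and -1.60 in M libraries alone (adjusted p of the difference between the letters 0.22). Its call was lost under 13 other settings, among them the GC and length offsets and 8 with 1 library left out, 5xFAD replicates 1181, 1190 and 1270 and P522R replicates 8, 21, 23, 27 and 106 (adjusted p = 0.051 to 0.095).

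Lipid handling genes were higher in P522R, 10 of 24 against 2 lower, with the same counts adjusted over the list alone (adjusted p = 0.42 with an estimated correlation). The lipase Pnpla2 rose by 0.90 (SE 0.10), Plin3 by 0.62 (SE 0.09), Plin2 by 0.63 (SE 0.11) and the lipid carrier Apoe by 0.50 (SE 0.08). Reactive astrocyte genes were higher in 13 of 27 and lower in 1, with 14 higher and 1 lower adjusted over the list alone (adjusted p = 0.38 with an estimated correlation). The complement component C4b rose by 0.92 (SE 0.20). Of 20 astrocyte genes 9 were higher, among them Aldh1l1 at 0.77 and Atp1b2 at 0.92, and 1 was lower, the glutamate transporter Slc1a2 at -0.44. The same counts held adjusted over the list alone (adjusted p = 0.38 with an estimated correlation). Immediate early genes were higher in 11 of 30, also 11 adjusted over the list alone (adjusted p = 0.58 with an estimated correlation), with Egr1 at 0.69 and Klf2 at 1.13. Complement genes were higher in 6 of 18, also 6 adjusted over the list alone (adjusted p = 0.57 with an estimated correlation). Lysosome genes were higher in 9 of 34 and lower in 1, with the same counts adjusted over the list alone (adjusted p = 0.74 with an estimated correlation), and the list was called under 10 of 18 other settings. The lysosomal regulator Tfeb rose by 0.77.

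Markers of vessels and borders were higher in P522R. Meninges and fibroblast genes were higher in 13 of 17, also 13 adjusted over the list alone (adjusted p = 0.33 with an estimated correlation), with Fn1 at 0.82 and Dcn at 0.63. Border macrophage genes were higher in 7 of 13, also 7 adjusted over the list alone (adjusted p = 0.33 with an estimated correlation), among them Lyve1 at 0.99 and Cd163 at 0.79. Mural cell genes were higher in 8 of 14, with 9 higher and 2 lower adjusted over the list alone (adjusted p = 0.42 with an estimated correlation). Endothelial genes were higher in 6 of 19, also 6 adjusted over the list alone (adjusted p = 0.74 with an estimated correlation), and the list was called under 12 of 18 other settings. Disease-associated microglia genes were higher in 5 of 34 and lower in 3, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.081). Among synaptic genes, a list that was not called (adjusted p = 0.96), Syn1 rose by 1.25 (SE 0.12) while Rims1 and Shank3 fell by 0.51 and 0.61.

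In all 6344 of 21280 genes differed between P522R and 5xFAD, 3198 higher and 3146 lower. Of the calls 50.4% were higher, against 78.7% in F libraries alone and 63.3% with the Bc1 share as a covariate. The median absolute log2 difference of the called genes was 0.39, and 292 exceeded 1. Of the 32 lists 10 were called, and 0 with an estimated correlation, where the smallest adjusted p was 0.33. By score per mouse astrocyte, mural, border macrophage, choroid plexus, meninges and thalamus lists were higher (exact permutation, adjusted p = 0.0025 to 0.029). The choroid plexus, meninges and thalamus scores were higher in M28L too, against the same 5xFAD libraries. They did not differ detectably between the variants (exact permutation, adjusted p = 0.76, 0.33 and 0.64). The log2 differences followed transcript GC content across genes (Spearman's rho 0.37; genes are not independent replicates). Where the same GC trend was simulated in every P522R library, 93.2% of the calls made without offsets were false, and with offsets 3.95%. In the data 6932 genes were called with offsets. There the trend varied between libraries, whose correlation with GC content ran from -0.28 to 0.44 in P522R and from -0.37 to 0.17 in 5xFAD. The simulated shares therefore do not give the share of false calls in the data. With 5 libraries left out in which Bc1 took over 10% of reads, 4 of them P522R, 2563 genes differed, and 889 with the Bc1 share as a covariate. The 4 were F replicates 8, 24 and 106 and M replicate 31, which left replicate 54 as the only P522R F library. Losses without these 5 libraries can therefore also come from fewer samples and unbalanced letters. Plin2, C4b, Tfeb and Cd163, and the lipid handling, complement, lysosome and endothelial lists, were not called without those libraries. These genes and Apoe, Aldh1l1, Klf2, Slc1a2, Shank3 and Sftpc were not called with the covariate, nor were Slc1a2 and Shank3 in F libraries alone. With the title prefix as a block Plin2, C4b, Tfeb and Sftpc were not called, and Sftpc was not called in M libraries alone, with 1 surrogate variable or with levels for Y-linked reads.

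Set against each other, P522R had higher microglial expression than M28L. Gpnmb was 2.31 higher (SE 0.23), Itgax 1.99 (SE 0.16, adjusted p = 1.0e-08) and the protease inhibitor Cst7 1.63 (SE 0.19). Of 34 disease-associated microglia genes 28 were higher and 2 lower, with the same counts adjusted over the list alone, and a median of 0.71 (adjusted p = 0.12 with an estimated correlation). Of 32 Plcg2 signalling genes 19 were higher and 4 lower, or 22 and 4 adjusted over the list alone (adjusted p = 0.17 with an estimated correlation). Complement genes were higher in 12 of 18, or 13 adjusted over the list alone (adjusted p = 0.12 with an estimated correlation). Lysosome genes were higher in 22 of 34 and lower in 1, or 24 and 1 adjusted over the list alone (adjusted p = 0.24 with an estimated correlation). Pan-myeloid genes were higher in 16 of 22, or 17 adjusted over the list alone (adjusted p = 0.24 with an estimated correlation). Homeostatic microglia genes were higher in 12 of 25 and lower in 2, or 13 and 2 adjusted over the list alone (adjusted p = 0.42 with an estimated correlation). Reactive astrocyte genes were higher in 11 of 27 and lower in 2, or 12 and 2 adjusted over the list alone (adjusted p = 0.17 with an estimated correlation), with Gfap at 1.20 and Serpina3n at 1.33. Among the largest falls were Thbs1 at -2.50 (SE 0.34), Lox at -1.95 (SE 0.51) and Grem1 at -1.62 (SE 0.35). Lox lay at 0.57 in M libraries alone, where it was not called, and the meninges and fibroblast list was not called (adjusted p = 0.29).

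In all 7405 genes differed between P522R and M28L, 3519 higher and 3886 lower. Of the calls 47.5% were higher, against 59.4% in F libraries alone and 90% of the 20 calls with the Bc1 share as a covariate. Of the 32 lists 16 were called, each higher in P522R, and 0 with an estimated correlation. Disease-associated microglia, complement, lysosome, lipid handling, astrocyte, reactive astrocyte, endothelial, mural and border macrophage scores per mouse were higher in P522R (exact permutation, adjusted p = 0.0050 to 0.049). Without the 5 libraries in which Bc1 took over 10% of reads, and so with fewer P522R samples, 2959 genes differed. With the Bc1 share as a covariate 20 differed, among them Itgax but not Gpnmb, Cst7, Gfap, Serpina3n, Thbs1, Lox or Grem1. Lox and Grem1 were not called without those libraries either, nor Grem1 in M libraries alone or with the prefix as a block, nor Lox with levels for Y-linked reads. The Bc1 share itself was 6.15 percentage points higher in P522R than in M28L.

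The effect of M28L differed between the letters for 6 genes, each with a rise in F libraries and no call in M libraries. Lox, which crosslinks collagen, rose in F libraries by 3.22 (SE 0.29), and differed by -0.45 (SE 0.30) in M libraries (adjusted p of the difference 3.3e-05). The 4 M28L F libraries held 10.9 to 22.8 CPM of Lox, against at most 2.44 CPM in any other library. Tnc rose by 2.24 in F libraries and differed by 0.19 in M libraries. Grem1, Fbln2 and Lpp were also among the 6, of which Lpp was named after its values were seen. Thbs1 rose in F libraries by 3.81 (SE 0.35) and in M libraries by 1.73 (SE 0.33), and this difference did not pass (adjusted p = 0.23). The 4 M28L F libraries also detected fewer genes, 25608 to 27627. The M28L M libraries detected at least 27723 and the 5xFAD F libraries at least 27831. A difference in the handling of these 4 libraries cannot be told apart from an effect of M28L that depends on the letter. For P522R against 5xFAD edgeR called 0 genes with a different effect in F and M, with 2874 at an unadjusted p below 0.05, while DESeq2 called 202 and limma-voom 1632. The effect of P522R against M28L differed for 1164 genes, a count that single libraries moved strongly.

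**Figure D3:**
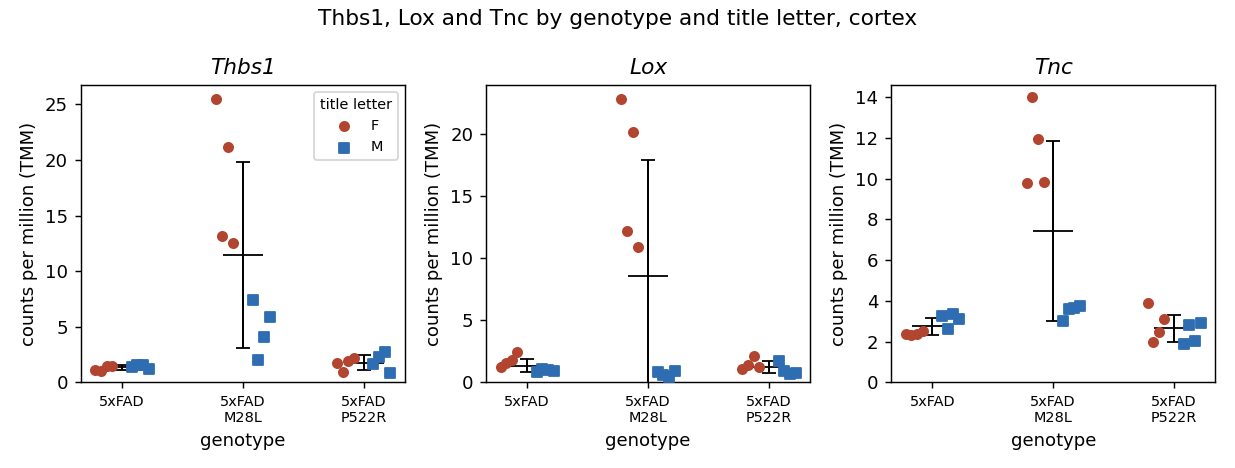
CPM (TMM-scaled) of Thbs1, Lox and Tnc in each library, by genotype; circles are F and squares M libraries, and the black bars give the mean and SD of 8 libraries. The 4 M28L F libraries held 10.9 to 22.8 CPM of Lox, and no other library more than 2.44 CPM.

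Between the letters 7197 genes differed over the 3 genotypes, 3697 higher and 3500 lower in M. The log2 differences followed gene length (Spearman's rho 0.43) and GC content (rho -0.20) across genes, which are not independent replicates. With offsets for both 6744 genes were called. Of 34 disease-associated microglia genes 29 were lower and 1 higher in M, with 30 lower and 2 higher adjusted over the list alone (adjusted p = 0.021 with an estimated correlation). Cst7 was 1.39 lower, written as -1.39 for M minus F (SE 0.16), Clec7a -1.37 and Trem2 -1.11, members chosen after their values were seen, as was Gfap of the reactive astrocyte list at -1.25. Interferon response genes were lower in M in 28 of 34, or 30 adjusted over the list alone (adjusted p = 0.042 with an estimated correlation). Synaptic genes were higher in M in 18 of 32, or 22 adjusted over the list alone (adjusted p = 0.037 with an estimated correlation). Of the calls 51.4% were higher in M with TMM, 36.8% with upper-quartile factors and 37.7% with offsets for GC content and gene length.

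The M28L and P522R effects against the same 5xFAD libraries had a Pearson correlation of 0.30 across 21280 genes, which are not independent replicates. Unchanged groups simulated against these shared controls gave 0.50 ± 0.0086 (SD, 20 simulations). The covariance was 0.0350, against 0.0266 in the simulations, a difference of 0.0083. With the controls split between the comparisons the correlation averaged 0.15 over 18 splits. Both variants had 44 genes called higher, against 16.1 for independent lists, and 18 called lower, against 22.3. There were 10 genes lower in M28L and higher in P522R, against 22.7, and 6 of the opposite kind, against 15.8. Neither reference covers both real effects and shared controls.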

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

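The tests of GC content and gene length and of the App level, and the fit with the Bc1 share as a covariate, were chosen only after the results they bear on were seen. The condition for reading the Bc1 slope, and that for the genes near Plcg2, were made stricter after their values were seen.

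In M28L against 5xFAD the effect differed between F and M for 6 genes, each with a larger effect in F libraries, and for 7 lists. Among these lists the cell cycle, mitochondrially encoded and meninges lists had lower effects in M than in F. The effects on the endothelial, immediate early, lysosome and lipid handling lists were higher in M. The cell cycle list was called also with an estimated correlation (adjusted p = 0.011 with an estimated correlation), and the others were not (adjusted p = 0.56 to 0.63 with an estimated correlation). The meninges list had a median difference of 0.01 and a mean of -0.27, so its call rested on part of its members. Single libraries lowered the 6 genes to 2 without M28L replicate 11, and to 3 without M28L replicate 15 or 5xFAD replicate 1248 or 1270. Of 100 splits that reassigned the letters within genotypes 4 gave as many genes, and the highest other split called 2645. Such splits do not keep the difference between the letters, which covered 7197 genes, so they do not decide whether chance gave the 6, although the condition set beforehand was met.

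In P522R against 5xFAD the effect on 4 lists differed between F and M. Disease-associated microglia and cholesterol genes had higher effects in M, and endothelial and antigen presentation genes lower ones (adjusted p = 0.87 for each with an estimated correlation). No gene passed with edgeR, against 2874 at an unadjusted p below 0.05 and 202 with DESeq2, and leaving out M28L replicate 28 gave 277 genes, and replicate 27 of P522R gave 2. All 100 such splits gave at least that count of 0 and the highest called 2913 genes, which says nothing about chance.

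In P522R against M28L the effect differed between F and M for 1164 genes and for 4 lists. The mitochondrially encoded and cell cycle lists had higher effects in M, and the endothelial and antigen presentation lists lower ones (adjusted p = 0.89, 0.38, 0.89 and 0.89 with an estimated correlation). Of 100 such splits 3 gave as many genes, with 4870 in the highest other, and for the same reason they do not decide about chance. The count fell to 83 without M28L replicate 15, 109 without 14, 204 without 9, 235 without 28, 242 without 11 and 482 without 17. It fell to 112 without P522R replicate 106, 178 without 21, 288 without 8, 608 without 27 and 755 without 24, and to 690 and 725 without 5xFAD replicates 1269 and 1190. It rose to 4085 without P522R replicate 54, 2913 without 31, and 3091 and 2961 without M28L replicates 12 and 16.

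Single libraries stood apart from the rest of their group in 11 of 126 groups of values examined, where chance gives about 6.3. The 5xFAD replicate 1180 had a total of 79230161 counts, against at least 99236503 in the others, and 85.5% of its counts on protein-coding genes, against 89.9 to 92.6% in the others. The 5xFAD replicate 1269 scored 0.47 for immediate early genes, against at most -0.29, and replicate 1177 scored 1.41 for endothelial genes, against at most 0.08. The M28L replicate 28 had 6.01% of counts on Bc1, 7.59% on mitochondrial genes and 89.6% on protein-coding genes. Its scores were -0.98 for lipid handling and 1.94 for mitochondrially encoded genes. The M28L replicate 14 scored 0.50 for myelin genes, against at most -0.06, and replicate 17 scored 2.78 for choroid plexus genes, against at most 0.28.

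In all 6344 genes differed, most by small amounts, between P522R and 5xFAD. Offsets that removed the GC content and gene length trends took Spearman's rho with GC content from 0.37 to -0.02 and left 6932 genes called, 4948 of them called in the same direction without offsets, which argues against these trends as the whole cause. The Bc1 share stays open as a marker of library composition, since with it as a covariate 889 genes passed, 857 of them shared in direction. It was 4.34 percentage points higher in P522R than in 5xFAD, short of the threshold (exact permutation, adjusted p = 0.054). Its slope across the 16 other libraries correlated with the P522R effect at -0.0096, where permuted shares gave an SD of 0.108, too wide to decide. The 5xFAD animals carry numbers from 1177 to 1270 and the variants numbers from 8 to 106. A cohort difference that set 5xFAD apart from both variants would reach M28L too. M28L differed in 258 genes from 5xFAD, while P522R differed in 7405 from M28L, which argues against it as the whole cause. Some measures nevertheless set 5xFAD apart from both variants. Fewer genes were detected in M28L and in P522R (exact permutation, adjusted p = 0.020 and 0.0037). Meninges scores were higher by 0.97 and 1.26, and choroid plexus and thalamus scores were higher in both variants too. A cohort difference in part of the genes therefore stays open. A cohort difference of P522R alone cannot be told apart from genotype, which may itself be the cause.

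Plcg2 was 1.04 higher (SE 0.14) in P522R than in 5xFAD. With the Bc1 share as a covariate the difference was 0.88 (SE 0.20, adjusted p = 0.011), which argues against composition as marked by Bc1 as the whole cause. Against M28L the covariate took it from 1.15 (SE 0.14) to 0.89 (SE 0.27, unadjusted p = 0.0027 with edgeR), and the call ended with a smaller difference and a larger SE, in a fit where few genes passed, which were not told apart. Of 85 tested genes within 5 Mb of Plcg2, 31.8% were higher in P522R against 15.0% elsewhere (Fisher's exact test p = 9.3e-05). With offsets the shares were 25.9% and 16.7% (Fisher's exact test p = 0.029). The test treats genes as independent, which they are not. Of the nearest genes, taken by position, Cmip was higher at 0.48 (SE 0.10). Sdr42e1 at -0.07, Mphosph6 at 0.08 and Hsd17b2 at 0.53 (SE 0.43) were not called (edgeR's adjusted p = 0.38 to 0.61). A regional change may still be part of the difference. The genes within 5 Mb had a median of 0.19 ± 0.40 (SD across genes), below the difference of Plcg2. In M28L, whose animal numbers lie near those of P522R, Plcg2 differed from 5xFAD by -0.11 (edgeR's adjusted p = 0.86). That argues against a cohort difference between 5xFAD and both variants as the cause of the Plcg2 difference, unless M28L offset it. An effect of the variant and a cohort difference of P522R alone stay open and untested.

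Disease-associated microglia genes were lower in M28L than in 5xFAD. Per mouse, the disease-associated minus the homeostatic mean log2 CPM was 0.44 lower, a difference of -0.44 (exact permutation p = 0.00078). This argues against an even loss of microglia of all states as the whole cause. It does not test a loss of cells in the disease-associated state. The homeostatic mean differed by -0.14 (exact permutation p = 0.26). By score per mouse the pan-myeloid list differed by -0.79 and the disease-associated list by -0.83 (exact permutation, adjusted p = 0.22 and 0.085). These permutations did not keep the letters apart, so differences between F and M add to their spread. In F libraries pan-myeloid scores were at most 0.37 in M28L and at least 0.79 in 5xFAD. In M libraries they overlapped, at most -0.83 in M28L and at least -0.92 in 5xFAD. Disease-associated scores did not overlap within either letter. A change in microglial number therefore stays open. The App difference was 0.098 (SE 0.072), which argues against lower expression of the App transgene as far as its reads count toward this gene. Reads of the mouse gene count there too, so a fall of the transgene alone could be diluted. Thy1, whose promoter drives the transgene, was lower in M28L but not called. In P522R the disease-associated minus the homeostatic mean differed from 5xFAD by 0.089 (exact permutation p = 0.35). It was 0.53 higher in P522R than in M28L (exact permutation p = 0.00047). For these genes the values argue against a cohort difference between 5xFAD and both variants as the cause, unless P522R offset it. Other measures did set 5xFAD apart from both variants, as given above. An effect of the M28L variant was not tested apart from these explanations. A cohort difference of M28L alone cannot be told apart from genotype.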

How the results depend on the processing

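Alternatives with GC and length offsets, the Bc1 share, 2 or 5 libraries left out and Y-read levels were chosen after the data were seen; the others were planned. Where no reason is given for a change below, the cause was not tested. In M28L against 5xFAD, 258 genes became 543 with DESeq2, 1937 with limma-voom, 707 with only these genotypes, 406 and 1347 with 1 and 2 surrogate variables and 628 with GC and length offsets. They became 49 without the letter, 98 with Y-read levels and 72 with the Bc1 share as a covariate. With fewer samples they became 102 in F and 5 in M libraries. Single libraries left out gave 157 to 308. In P522R against 5xFAD, 6344 became 2927 in F libraries (fewer samples) and 3615 with 1 surrogate variable. They became 2563 without the 5 libraries high in Bc1 (also fewer samples) and 889 with its share as a covariate. Single libraries gave 5383 to 7489. In P522R against M28L, 7405 became 4619, 2959 and 20 under the latter 3, and 6443 to 8402 without single libraries.

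In 9 pairs of libraries that share a title prefix the deviations correlated from -0.24 to 0.35, and 3 exceeded 0.1. These values were not compared with pairs that share no prefix, so they do not decide whether a prefix pairs libraries. With the prefix as a block, which uses only libraries that share a prefix, 101, 936 and 1259 genes passed in the 3 comparisons.

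Genes with a different effect in F and M became 22 (DESeq2), 35 (limma-voom) and 17 (no filter) for M28L, and 2 to 7 without single libraries. For P522R against 5xFAD, 0 became 202, 1632 and 12, and 0 to 277. For P522R against M28L, 1164 became 2743, 2062, 1756 at a mean of 1 CPM, and 83 to 4085. Lists called with an estimated correlation were 10, 0 and 0, against 19, 10 and 16, and 17 in P522R against 5xFAD with no filter. Plcg2 in M28L turned from -0.11 to 0.023 with limma-voom, neither called, and in P522R against M28L it was 0.89 with the Bc1 share. The correlation of effects became 0.15 with split controls, 0.10 at a mean of 1 CPM and 0.20 by Spearman's rho. Sftpc in P522R turned to -0.13 without the 5 libraries. In P522R against M28L, Lox turned to 0.57 in M libraries and 0.030 under the block, and was not called in M libraries in M28L against 5xFAD. Of 52 genes followed in M28L against 5xFAD, not all of them named in the text, 757 of 934 values under other settings kept direction and side of the threshold. The figures were 850 of 899 for 50 genes in P522R against 5xFAD and 606 of 665 for 37 genes in P522R against M28L. The lists of disease-associated microglia and antigen presentation stayed called under all 18 settings with the preset correlation in M28L against 5xFAD. Genes near 1 CPM rest on about 100 reads per library, and the simulations recovered 64 to 76% of changes of 0.5.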

Other observations

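The tests of other splits of the samples were set before the results were seen.

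In P522R against M28L, 9 further lists were called higher with the preset correlation. Endothelial genes were higher in 9 of 19 (Cldn5 at 0.88), mural genes in 8 of 14 and border macrophage genes in 6 of 13 (adjusted p = 0.35, 0.33 and 0.17 with an estimated correlation). Lipid handling genes were higher in 14 of 24 and lower in 2, with Plin2 at 0.77 and Apoe at 0.59, and astrocyte genes higher in 11 of 20 and lower in 1 (adjusted p = 0.19 and 0.22 with an estimated correlation). Antigen presentation genes were higher in 13 of 22, with Cd74 at 1.43, and interferon genes in 14 of 34 with 2 lower, among them Oas1a at 1.09 (adjusted p = 0.35 and 0.63 with an estimated correlation). Inflammatory cytokine genes were higher in 10 of 28 and lower in 1, with Ccl3 at 1.28, and risk gene orthologs higher in 12 of 29 and lower in 4 (adjusted p = 0.17 and 0.24 with an estimated correlation). Adjusted over the list alone, the counts higher were 9, 8, 6, 14, 11, 14, 16, 10 and 12 in the order given, and lower 0, 0, 0, 2, 3, 0, 4, 2 and 4.

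Some other lists were called in none of the 3 comparisons with the preset correlation. In P522R against 5xFAD, cholesterol synthesis genes had 5 higher and 6 lower of 22, with Stard4 at -0.53 and Hsd17b7 at -0.56. Oligodendrocyte precursor genes had 4 higher and 2 lower of 14, with Sox10 at 0.98. Excitatory neuron genes had 3 higher and 5 lower of 19, and inhibitory neuron genes 5 and 2 of 17. Striatum genes had 6 higher and 4 lower of 15, hippocampus genes 3 and 3 of 14, erythrocyte genes 0 and 1 of 6, and mitochondrially encoded genes 0 and 0 of 13. Adjusted over the list alone these were 5 and 6, 4 and 2, 3 and 7, 6 and 2, 6 and 4, 5 and 3, 0 and 1, and 0 and 0.

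Classes of genes that are not protein-coding are given here as medians, with no test of the class. The class of genes to be experimentally verified, short TEC, had a median log2 difference of -0.34 in P522R and -0.31 in M28L against 5xFAD, over 1089 genes. Of these 140 were called lower and 16 higher in P522R, and 6 and 1 in M28L. The long intergenic RNAs had -0.20 and -0.08 over 1075 genes, processed pseudogenes -0.02 and -0.07 over 1111, and protein-coding genes -0.01 and 0.02 over 15804.

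Reads on Y-linked genes, 41 to 89 per library, were present in 4 of 4 M28L F libraries, 2 of 4 P522R F libraries and 1 of 4 5xFAD F libraries. The M libraries held at least 7048 such reads.

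Among 100 splits of the samples, the real split alone gave as many genes in M28L against 5xFAD (258, highest other 15), in P522R against 5xFAD (6344, highest other 5031), in P522R against M28L (7405, highest other 3350) and between the letters (7197, highest other 0). In each of these 4 counts 1 split of 100 was as large, the real one, which makes chance unlikely. With 100 splits the share cannot fall below 1 of 100, so chance is not excluded. In P522R against 5xFAD another split came as high as 5031 genes, against the real 6344. For the count of lists other splits reached the real count, so chance stays open. In M28L against 5xFAD 9 of 100 splits called as many as the real 19 (highest other 22), in P522R against 5xFAD 35 called as many as 10 (highest other 19), and in P522R against M28L 11 called as many as 16 (highest other 18).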
